A study of Homo sapiens with 6 samples.

How the data were processed

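Binding of FOSL2 and JUNB was measured by ChIP-seq in HaCaT keratinocytes, with 3 libraries per factor. Per the labels, cells were crosslinked, nuclei were sonicated and libraries were prepared by ChIPmentation. The antibodies differed between the factors, per the labels. Tools and the build named in the submitters' processing notes, without order or options, were Bowtie2, SAMtools 1.8, Picard 1.89, MACS2, deepTools and hg38. The order of these steps, the control used for peak calling and the rule by which regions of the 3 libraries were combined are not given in the sources used here. Each factor had 1 deposited list of narrow peaks, named as a conservative overlap, that stood for its 3 libraries together. No value per library was used, so no spread between replicates, no leave-one-out value and no depth per library could be given.

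The deposited lists give a whole-number score for each region, which equals 10 times the −log10 p to within 1. The deposited fold enrichment, a linear ratio of signal over background, is the authors' own value per region. The deposited −log10 p and −log10 q columns were read as the peak caller wrote them, and a summit offset gives the position of the highest signal. The lowest −log10 q was 0.795 for FOSL2 and 0.670 for JUNB, and 21 and 77 regions had a −log10 q under 1.30. The FOSL2 list had 75704 rows, of which 1 outside the autosomes and X was left out, and the JUNB list had 40061. No regions overlapped within a list, so each row was 1 region. Coordinates are given from 1 in hg38.

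Gene positions and symbols were taken from the RefSeq gene table of GRCh38.p14, which shares its chromosome coordinates with hg38. It holds the start, end and type of 19974 protein-coding genes and 16458 pseudogenes on the chromosomes used, without strand. All 366 entries of the gene lists (359 genes) matched a symbol. Because strand was not used here, distances to a transcription start, as fixed beforehand, were replaced by distances to either end of a gene. A region counted as near a gene when any of its bases lay within 10 kb of an end. For the place of regions, a summit within 1000 bp of an end of a protein-coding gene was called near a gene end, and otherwise inside or outside genes. Exons and introns were not separated. Genome sequence was not used here, so the tests of the AP-1 motif and of a panel of 25 motifs at summits, also fixed beforehand, were not run.

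Regions were called shared when they had at least 1 bp in common with a region of the other list. The overlap was compared with 1000 uniform placements of the JUNB regions on the same chromosome, between position 1 and the highest annotated position. Fold enrichment of shared and single-factor regions was compared within each list by a permutation test of the difference in median log2 fold enrichment with 100000 resamples. Shares near gene ends were compared with 1000 uniform placements and between classes by Fisher's exact test, with conditional odds ratios and exact 95% intervals. Shares of single lists have 95% Wilson intervals. The 16 gene lists, 10 of them related to keratinocytes, AP-1 signalling or atopic dermatitis, were compared with 10000 random sets of protein-coding genes matched on deciles of the number of genes within 100 kb. P-values were adjusted by Benjamini-Hochberg within each factor, and the threshold was 0.05. The lists, the main tests and most alternatives were fixed before the data were examined. Genes were named by a rule fixed then: in each list the 4 genes with the highest JUNB fold enrichment among those with regions of both factors, up to 3 genes without any region in each of the 10 lists in alphabetical order, the 5 strongest regions of each list and class, and AP-1 genes, FLG, IVL, LORICRIN, KRT5, KRT14, KRT1, KRT10, OVOL1, IL13 and TP63 always. Some genes that the rule selects are not reported here. DST and LCE3A were named outside the rule, after their values were seen.

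Alternatives were a reciprocal overlap of 50%, summits within 100 bp, a shift of 50 kb in place of random placement, regions with −log10 q of at least 10, the 10000 regions of highest fold enrichment, gene ends within 500 and 2500 bp, ends of all annotated genes, and distances of 5 and 50 kb or no matching for gene lists. Chosen after seeing the data were matching on density and gene length, the whole gene span, counting genes within 100 kb of each other once, and leaving out regions narrower than 400 bp. The overlap code was tested on simulated data with 40061 regions: planted overlaps of 0, 5 and 30% were recovered as 0.138, 5.07 and 30.2%. The gene set code was tested on 19000 simulated genes with sets of 20: with no effect 2% of sets passed p under 0.05, with a region given to 40% of the missing genes 50% did, and with 70% 97% did. These p-values were not adjusted. Simulated genes had regions independently of each other, at rates not taken from the deposited lists. The shares therefore check the code and do not give the power of the adjusted tests on the real lists. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.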

Results

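FOSL2 and JUNB, a FOS-family and a JUN-family subunit of the dimeric transcription factor AP-1, were mapped in HaCaT cells, a spontaneously immortalised line of human skin keratinocytes. Binding was measured by chromatin immunoprecipitation followed by sequencing, with libraries made by ChIPmentation, in which a transposase adds the sequencing adapters to the immunoprecipitated chromatin. The 6 libraries fell into 3 for FOSL2 and 3 for JUNB, in a study of enhancer variants at atopic dermatitis risk loci. A single list of binding regions per factor was analysed, each made from its 3 libraries together, so no value below has a replicate error and the depth of the libraries is unknown. Regions and genes are not replicates, and the intervals and tests over them cover counting error in these lists only.

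FOSL2 occupied 75703 regions on the autosomes and X, covering 51.4 Mb, and JUNB occupied 40061 regions, covering 23.9 Mb. FOSL2 regions had a median width of 643 bp (interquartile range 419 to 903) and a median fold enrichment of 5.56 (3.83 to 8.07). JUNB regions had a median width of 569 bp (359 to 789) and a median fold enrichment of 4.79 (3.62 to 6.51). Fold enrichment is the authors' value for each region and was compared between classes of regions within its list. Its level was not compared between the lists. A FOSL2 region lay within 10 kb of either end of 14030 of the 19974 protein-coding genes (70.2%), and a JUNB region did so for 11205 (56.1%). A stretch bound by both lay within 10 kb of 8643 genes (43.3%).

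The first comparison asked whether the 2 AP-1 subunits were found at the same places. Most JUNB regions lay on FOSL2 regions: 31441 of 40061 (78.5%, 95% Wilson interval 78.1 to 78.9) shared at least 1 bp with a FOSL2 region, and 8620 were JUNB-only. In the longer FOSL2 list, 31150 of 75703 regions (41.1%, 40.8 to 41.5) touched a JUNB region and 44553 were FOSL2-only. In shared regions the 2 summits lay a median of 31 bp apart (interquartile range 11 to 66), with 66.4% of pairs within 50 bp and 3.25% farther apart than 250 bp. One end of SPRR1A, a cornified envelope precursor gene, held such a pair, with summits 56 bp (FOSL2) and 78 bp (JUNB) from the gene's end and fold enrichments of 9.81 and 7.96. Over 1000 uniform placements on the same chromosomes, a mean of 1343.5 ± 36.3 (SD) JUNB regions met a FOSL2 region and the highest count was 1459, so the observed count was 23.4 times the mean (one-sided permutation test, p = 0.000999, the smallest the draws can give). With the JUNB regions shifted by 50 kb instead, 2371 met a FOSL2 region, which lowered the ratio to 13.3. Neither comparison was limited to open chromatin or to sequence where reads can be placed. The excess therefore cannot tell joint binding of the 2 factors from a common preference for open chromatin.

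Shared regions were the stronger ones in both lists. FOSL2 regions with a JUNB region had a median fold enrichment of 7.85, against 4.40 for FOSL2-only regions, a difference of 0.83 in median log2 fold enrichment. JUNB regions with a FOSL2 region had a median of 5.31, against 3.45 for JUNB-only regions, a log2 difference of 0.62. Both differences gave p = 1e-05 in a two-sided permutation test of 100000 resamples, the smallest these can give. Of the 10% of FOSL2 regions with the lowest fold enrichment 7.40% were shared, and of the highest 10% 84.0% were, which left 1208 strong FOSL2 regions without JUNB. The corresponding shares of JUNB regions were 39.0% and 97.6%, which left 97 strong JUNB regions without FOSL2. Across the shared regions the 2 fold enrichments had a Pearson correlation of 0.71 on the log2 scale and a Spearman correlation of 0.72, across regions that are not independent replicates. With only regions of −log10 q of at least 10, the JUNB difference fell to 0.35, with the same p. Each list was cut from a longer ranking by p-value that lost most of its low places. Of the numbers from 100001 to 200000, 5.35% were kept for FOSL2 and 0.997% for JUNB. A weak region may thus lack a partner because the partner, also weak, was left out. These comparisons cannot tell such losses from stronger binding at shared places.

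**Figure D1:**
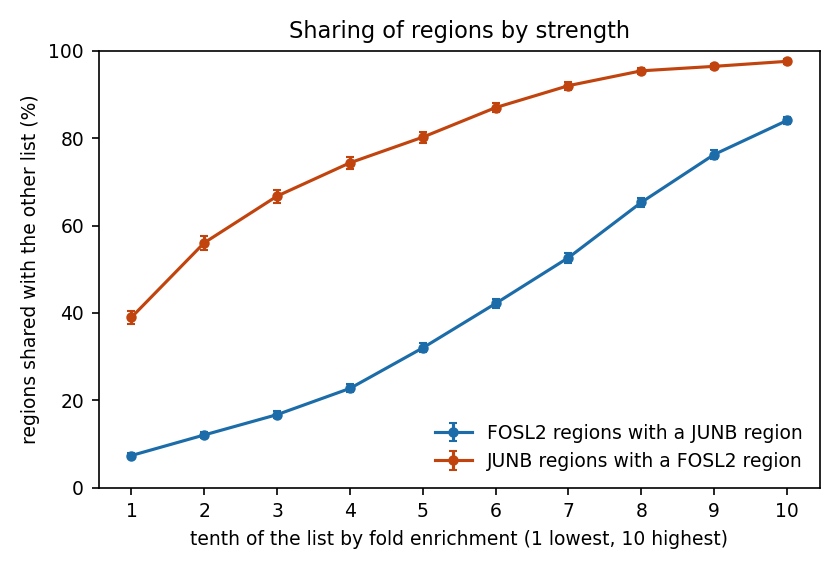
The share of regions (%, vertical axis) that overlap a region of the other list is plotted for each 10% of the list by fold enrichment (horizontal axis, lowest to highest), with 95% Wilson intervals as bars. The share rises from 7.40% to 84.0% for FOSL2 regions and from 39.0% to 97.6% for JUNB regions.

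The next comparison asked where the regions lay relative to protein-coding genes. JUNB-only regions stood out at gene ends: 28.3% of their summits (95% Wilson interval 27.4 to 29.3) lay within 1 kb of an end, 10.2 times the share under uniform placement. The share was 8.50% for shared regions (3.33 times uniform) and 5.61% for FOSL2-only regions (2.25 times). Among the strongest JUNB-only regions were those at FZD1, a Wnt receptor, 3 bp from the gene's end with a fold enrichment of 12.6, and at EEF1A1, a translation elongation factor, 217 bp from its end with 12.6. All of FOSL2 gave 6.79% (2.69 times uniform) and all of JUNB 12.8% (4.90 times), and each of the 5 sets exceeded uniform placement at p = 0.000999 (two-sided permutation test of 1000 placements, the smallest possible). The odds of lying near a gene end were 6.64 times higher for JUNB-only than for FOSL2-only regions (95% interval 6.24 to 7.07) and 4.25 times higher than for shared regions (4.0 to 4.52), and both p-values of Fisher's exact test were below the smallest number the software represents. Shared regions had an odds ratio of 1.56 against FOSL2-only regions (1.48 to 1.65, two-sided Fisher's exact test, adjusted p = 7.1e-54 over 3 comparisons). Of all summits, 46.1% of shared, 46.4% of FOSL2-only and 37.7% of JUNB-only summits lay inside a gene farther than 1 kb from its ends. The 10.2-fold excess of JUNB-only regions became 15.7 within 500 bp of an end, 5.45 within 2500 bp and 5.24 at the ends of all annotated genes. The odds ratios of 6.64 and 4.25 ranged from 4.73 and 3.24 at the ends of all annotated genes to 12 and 7.32 with regions narrower than 400 bp left out, an alternative chosen after seeing the data, and were 10.1 and 6.62 with −log10 q of at least 10.

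**Figure D2:**
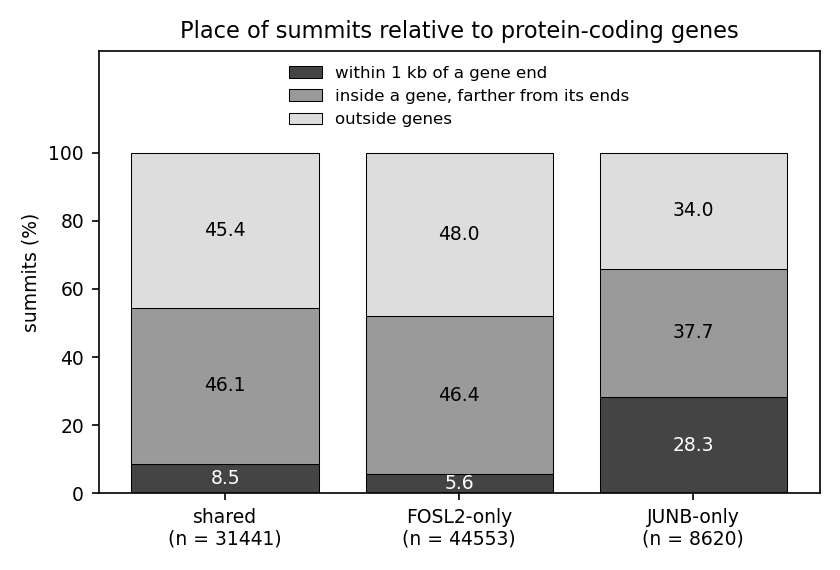
Stacked bars give the share of summits (%, vertical axis) within 1 kb of an end of a protein-coding gene, inside a gene farther from its ends, and outside genes, for shared (JUNB regions), FOSL2-only and JUNB-only regions. The part near gene ends is 28.3% of JUNB-only summits, against 8.50% and 5.61%.

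The last comparison asked which groups of genes had a region within 10 kb of an end more often than random genes of the same local gene density. Regions of a named gene are those within 10 kb of its ends, and regions farther inside a long gene are not counted. The highest FOSL2 and JUNB values of a gene can come from different sites, as they did at KRT1, KLK7 and MMP1. Genes of the basal layer and its adhesion to the basement membrane had the highest share with a region: all 20 had a FOSL2 region (random sets 69.8%, adjusted permutation p = 0.0064) and 19 of 20 had a JUNB region (random sets 55.8%, adjusted permutation p = 0.0016). High JUNB fold enrichments in this group were at COL17A1 (8.39), ITGB6 (7.75) and COL7A1 (7.28), which encode hemidesmosomal collagen XVII, an integrin subunit and anchoring-fibril collagen VII. KRT14, a basal keratin, had 4 FOSL2 and 4 JUNB regions, with highest fold enrichments of 7.12 and 5.55, 173 and 167 bp from the gene's end. Its partner KRT5 had 2 FOSL2 regions (up to 3.52) and 5 JUNB regions (up to 4.22). TP63, the transcription factor of the epidermal lineage, had weaker regions, 2 of FOSL2 up to 3.81 and 1 of JUNB at 2.18, and none was shared. DST, a long gene, was the 1 gene of the group without a JUNB region within 10 kb of an end.

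Genes of suprabasal cells and their junctions had a FOSL2 region in 29 of 30 cases (random sets 70.3%, adjusted permutation p = 0.0064) and a JUNB region in 26 of 30 (random sets 56.6%, adjusted permutation p = 0.0032). CDSN, which encodes corneodesmosin, carried the strongest pair, with fold enrichments of 13.2 (FOSL2) and 10.4 (JUNB) at a shared site 403 and 413 bp from its end, the JUNB region running from 31114241 to 31115285 on chromosome 6. KRT1, an early keratin of differentiation, had 2 shared regions with up to 10.2 and 9.35, KLK7 (a desquamation protease) reached 9.93 and 9.08, and CLDN4 (a tight-junction claudin) reached 10.3 and 8.87. KRT10 had weaker regions (3.16 and 2.85, none shared), OVOL1 had 2 FOSL2 regions (up to 7.26) and 3 JUNB regions (up to 5.18), none shared, and CASP14 had none of either factor within 10 kb of its ends.

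Stress keratin and wound repair genes had a FOSL2 region in 19 of 20 cases (adjusted permutation p = 0.0314) and a JUNB region in 17 of 20 (adjusted permutation p = 0.0256), against 70.5% and 56.5% of random sets. PLAUR, the urokinase receptor, reached 11.8 (FOSL2) and 11 (JUNB), and the collagenase gene MMP1 reached 7.63 and 7.64. MMP10 shared its strongest JUNB region with MMP1, on chromosome 11 from 102783383 to 102784411. KRT6C had no region of either factor within 10 kb of its ends.

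Genes of the response to EGF receptor and MAPK signalling had a FOSL2 region in 22 of 24 cases and a JUNB region in 22 of 24, against 66.6% and 50.6% of random sets (adjusted permutation p = 0.0272 and 0.0016). EREG, an EGF receptor ligand, reached 13.8 (FOSL2) and 9.39 (JUNB), ERRFI1, a feedback inhibitor of the receptor, had 6 regions of each factor up to 7.96 and 8.77, and IER2 and ZFP36 reached 7.67 and 7.45 for JUNB. TGFA had no region of either factor within 10 kb of its ends. Targets of YAP and TEAD had a FOSL2 region in 18 of 20 cases and a JUNB region in 17 of 20, against 67.3% and 52.4% (adjusted permutation p = 0.0472 and 0.0084). ANKRD1 led with 11.5 (FOSL2) and 10.3 (JUNB) at a shared site 277 and 264 bp from its end, followed for JUNB by AMOTL2 (8.98), AMOTL1 (8.19) and TEAD1 (7.55), while FSTL1 and WWTR1 had none within 10 kb of their ends.

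AP-1 and related genes had a region of either factor in 17 of 21 cases, which exceeded random sets for JUNB (55.0%, adjusted permutation p = 0.0272) and not for FOSL2 (69.3%, adjusted permutation p = 0.316), although over the whole gene span it also did for FOSL2 (adjusted permutation p = 0.0259). FOSL2 itself was bound by both factors at its end, with fold enrichments of 8.32 (FOSL2) and 6.57 (JUNB), the JUNB region running from 28392310 to 28393237 on chromosome 2. JUN had 1 region of each at its end (5.38 and 7.45), and FOS had a shared region of 3.54 and 3.44. JUNB had 4 FOSL2 regions up to 3.72 and 2 JUNB regions up to 4.36, none shared. The highest JUNB fold enrichments were at BATF2 (8.85), MAFF (8.61), ATF3 (8.0) and JUND (7.68). Those of FOSB, FOSL1, BATF, BATF3, ATF2, ATF7, MAF, MAFG and MAFK ran from 3.23 to 6.82, and BACH1, BACH2 and JDP2 had no region of either factor within 10 kb of their ends.

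Receptors and signal mediators of type 2 cytokines and IL-22 had a FOSL2 region in 21 of 23 cases (random sets 68.0%, adjusted permutation p = 0.0314) and a JUNB region in 14 of 23 (52.1%, adjusted permutation p = 0.466). STAT6 reached 9.98 (FOSL2) and 9.75 (JUNB), JAK2 9.34 and 9.27, IL10RB 8.91 and 8.60, and IL7R 9.74 and 8.05, while CRLF2 had none within 10 kb of its ends. Whether the 2 factors differed in any group was not tested.

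Groups that did not exceed random sets included the cornified envelope genes, with a FOSL2 region in 24 of 30 cases (adjusted permutation p = 0.417) and a JUNB region in 16 of 30 (adjusted permutation p = 0.988). Within this group FLG, which encodes filaggrin, had 1 FOSL2 region of 5.57, 72 bp from its end, and no JUNB region within 10 kb of an end, IVL had 3 regions of each factor (up to 6.06 and 6.65), and LORICRIN, LCE1A, LCE1B and LCE2A had none. FLG2 (10.3 and 9.04), SPRR1A (9.81 and 7.96), KPRP (8.73 and 7.65) and SPRR1B (7.28 and 7.45) had the highest JUNB values. Keratinocyte inflammation genes had a FOSL2 region in 23 of 28 cases (adjusted permutation p = 0.258) and a JUNB region in 19 of 28 (adjusted permutation p = 0.257), with JUNB values of 11 at IL18, 8.78 at TNFAIP3, 8.75 at CCL20 and 8.18 at CSF3 and no region within 10 kb of the ends of CXCL10, CXCL3 and DEFB4A. This group passed the threshold under 3 of 9 alternatives for FOSL2 and 2 of 9 for JUNB. Genes at atopic dermatitis loci had a FOSL2 region in 28 of 39 cases and a JUNB region in 23 of 39 (adjusted permutation p = 0.698 and 0.598). IL7R, CYP24A1 (10.0 and 6.89), RTEL1 and TNFRSF6B had the highest JUNB values, the last pair through the same region of 6.84 on chromosome 20 from 63698875 to 63699652, and IL13, CD207 and IL18R1 had none within 10 kb of their ends.

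Marker genes of other cell types did not exceed random sets. Melanocyte genes had a FOSL2 region in 8 of 15 cases and a JUNB region in 4 of 15, fibroblast genes in 10 and 7 of 18, T-cell genes in 12 and 10 of 18, hepatocyte genes in 9 and 7 of 18 and neuronal genes in 11 and 10 of 18 (adjusted p from 0.707 to 0.988). Single members still carried regions of both factors. High JUNB values were 9.03, 5.92 and 5.63 at PMEL, SLC24A5 and RAB38 (melanocyte) and 10.3, 8.83, 8.39 and 6.68 at VIM, COL5A1, FBLN1 and COL1A1 (fibroblast). They were 8.24, 8.22, 5.92 and 4.94 at LCK, CD5, CD3E and LAT (T cell), 8.45, 5.64 and 5.43 at CYP2E1, AHSG and CYP3A4 (hepatocyte), and 6.81, 6.58, 6.53 and 4.55 at SYP, DLG4, MAP2 and SYT1 (neuron). Housekeeping genes had a FOSL2 region in 20 of 24 cases and a JUNB region in 19 of 24 (adjusted permutation p = 0.290 and 0.0521), with EEF1A1 (12.6), SDHA (8.50) and SNRPD3 (6.09) among the higher JUNB values. Their JUNB share was 79.2%, against 57.8% of random sets, and this excess passed the threshold under 5 of 9 alternatives. Random sets were not matched on expression. The calls of the keratinocyte-related groups therefore cannot be told apart from a preference for genes active in HaCaT cells. The adjusted p-values are from one-sided permutation tests against 10000 random gene sets, over 16 lists within each factor. No list passed the threshold for either factor with a distance of 50 kb, where 92.6% and 83.1% of all genes had a FOSL2 or JUNB region, or with the 10000 regions of highest fold enrichment. With those 10000, JUNB shares of the called lists stayed above random, from 16.7% against 13.2% (EGF receptor response) to 38.1% against 14.1% (AP-1 genes). FOSL2 shares of the called lists went both ways, from 5% against 12.8% (basal genes) to 26.1% against 13.1% (cytokine receptors). The FOSL2 calls of the YAP and TEAD targets and of the cytokine receptors were each lost under 5 of 9 alternatives, that of the stress genes also with −log10 q of at least 10, that of the basal genes also over the whole gene span, and the JUNB call of the AP-1 genes also with clustered genes counted once.

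**Figure D3:**
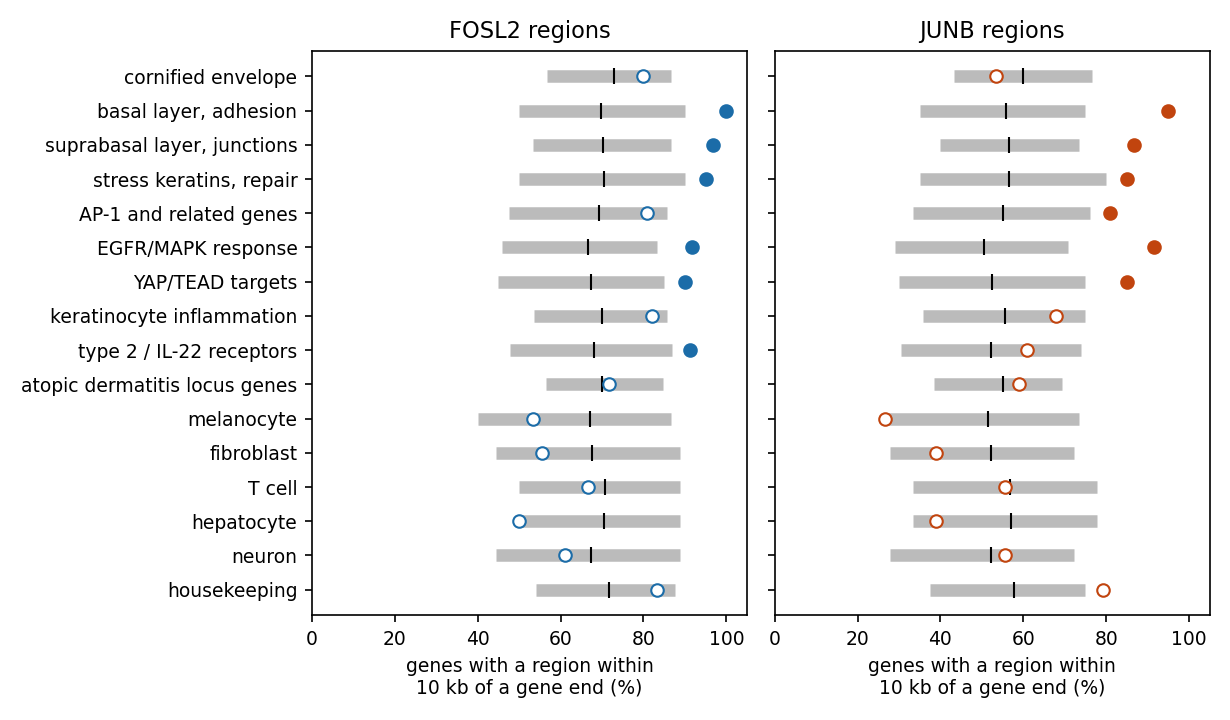
Points give the share of genes in each of 16 lists with a FOSL2 (left) or JUNB (right) region within 10 kb of a gene end (%, horizontal axis), filled where the adjusted p is under 0.05, with the mean (tick) and the central 95% (grey bar) of 10000 random gene sets. For each factor 6 lists lie above random, and the highest shares are those of the basal layer list with 20 and 19 of 20 genes.

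The epidermal differentiation complex on chromosome 1, where most of the cornified envelope genes lie side by side, held 88 FOSL2 and 61 JUNB regions between 152034141 and 153510651. This was 59.6 FOSL2 and 41.3 JUNB regions per Mb, against 30.2 and 17.0 over the whole chromosome. The comparison was not matched on local gene density or limited to sequence where reads can be placed, and the difference was not tested. It therefore does not show an excess for the genes of the complex. Against random genes of the same local gene density, the cornified envelope genes did not exceed random sets for either factor, as given above. Fold enrichments reached 10.7 (FOSL2) and 9.44 (JUNB), and 49 of the JUNB regions were shared. No region of either factor lay within 10 kb of LCE1A, LCE1B, LCE2A, LCE3A or LORICRIN.

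**Figure D4:**
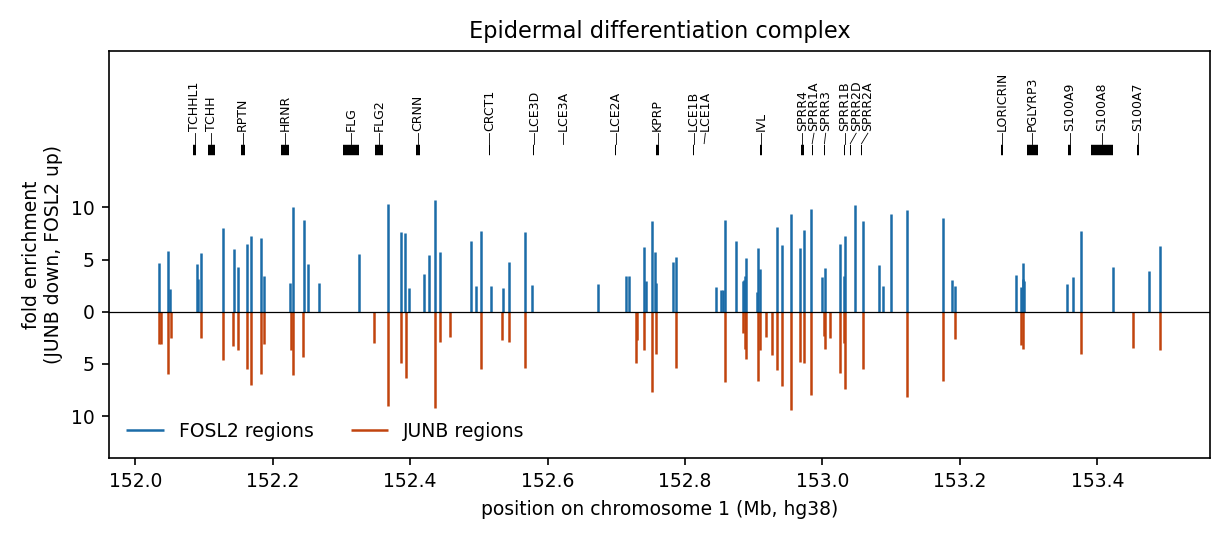
Each vertical line is a FOSL2 (up) or JUNB (down) region at its position on chromosome 1 (Mb, hg38, horizontal axis), its length the authors' fold enrichment (vertical axis), with the 26 genes of the cornified envelope list drawn above. JUNB reaches 9.44 and FOSL2 10.7, and 49 of the 61 JUNB regions are shared.

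The 5 strongest FOSL2 regions had fold enrichments from 26.8 to 38.5, and all 5 were shared with JUNB. The gene with the nearest end was CNTNAP3 (38.5, chromosome 9 from 39030636 to 39030878, 33949 bp away), LOC124907867 (30.1, 40204 bp), FAM72A (27.2, 9889 bp), GTF2IRD2 (27.2, inside the gene) and NUTM2A (26.8, 14139 bp). The 5 strongest JUNB regions lay nearest to PLGLB2 (23.2), LOC102723475 (21.8), LOC124907867 (21.7), CNTNAP3 (21.4) and LOC107987004 (21), and all 5 were shared with FOSL2. Of the FOSL2-only regions the strongest were nearest to VPREB1 (21.1), LRRC61 (17.5), LIPI (17.1), ZNF473 (16.9) and NR4A2 (16.7), at 24974 to 358827 bp from the end of that gene, and the region nearest to LRRC61 lay inside ACTR3C. The strongest JUNB-only regions were nearest to SPDYE16 (19.8, chromosome 7 from 76548913 to 76549846), NXF3 (14.2), POM121 (13.2, 117 bp from its end), EEF1A1 and FZD1. Where a region lies in sequence with near-identical copies, its reads can be shared between them, and the fold enrichment is uncertain.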

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

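The test on housekeeping genes was chosen only after the other results were seen, and the remaining tests here were set after the overlap and its relation to strength were seen, but before their own results.

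The names of the deposited regions carry numbers from a longer ranking by p-value, which the comparisons did not use. In the FOSL2 list 130405 of the numbers up to 206108 were missing and in the JUNB list 189350 of those up to 229411, so 36.7% and 17.5% were kept. Among the first 1000 numbers 980 and 922 were kept. A place without a region in a list is therefore not shown to be unbound.

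JUNB regions in the highest 10% of fold enrichment without a FOSL2 region numbered 97 and included those at FZD1, EEF1A1, ATG12, JARID2, SNX15 and E2F4, the last 4 named after their values were seen. A FOSL2 region just beyond the overlap does not account for most of them, since 7.22% had one within 1 kb (95% interval 3.54 to 14.2). They lay within 1 kb of a gene end more often than strong shared regions, 30.9% against 3.58% (odds ratio 12, 7.30 to 19.5). In the 10% just below in fold enrichment the shares were closer, 10.5% of JUNB-only against 5.02% of shared regions. Over all JUNB-only regions, which include the strong ones, the share was 28.3%. The place at gene ends was therefore not particular to the strong ones. A pseudogene within 50 kb was also more frequent for the strong JUNB-only regions, 52.6% against 39.8% (odds ratio 1.67, 1.10 to 2.57). Sites of another kind at gene ends and duplicated sequence thus both stay open. Housekeeping genes had a JUNB-only region at their ends in 7 of 24 cases, with an odds ratio of 2.52 against other genes whose interval (0.881 to 6.39) leaves open whether the JUNB antibody gave signal at active gene ends in general. A FOSL2 region lost between the longer ranking and the final list stays open too, and no biological explanation was tested beyond the place of the regions.

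FOSL2 had 75703 regions against 40061 for JUNB, and 44553 of them had no JUNB region. The longer rankings reached 206108 for FOSL2 and 229411 for JUNB, so the JUNB ranking did not appear shorter. Fewer JUNB numbers were kept, such as 31.4% against 76.7% of those from 40001 to 60000. The shorter JUNB list thus went with a larger loss between ranking and final list, by a rule that is not given. Suppose the JUNB list differed only by a lower sensitivity that was the same at all places. FOSL2-only and shared regions of equal FOSL2 fold enrichment would then lie near gene ends equally often, if equal fold enrichment also meant equal ease of detection. They did not: the Mantel-Haenszel odds ratio over 10 classes of fold enrichment was 0.437 (0.409 to 0.465). Equal fold enrichment need not mean equal ease of detection, however. The strongest FOSL2 region of KRT5 had a fold enrichment of 3.52 and a −log10 q of 62.8, that of SPRR3 4.18 and 14.7. The odds ratio therefore cannot decide whether lower sensitivity alone was at work. It also cannot weigh a sensitivity that differs between gene ends and other places, or JUNB signal at active gene ends in general, left open above. The difference was also not the same in all classes. In the lowest of these 5.82% of FOSL2-only and 16.8% of shared regions were near a gene end, and in the second highest 3.45% and 4.49%. In the highest the shares were 4.22% and 3.35%. The different antibodies and a true difference between the factors stay open, as untested.

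Regions narrower than 400 bp made up 43.4% of the 76 FOSL2 regions in the highest 0.1% of fold enrichment, against 0.907% of the rest of the highest 10%. CNTNAP3, FAM72A and NUTM2A were the nearest genes of 3 of them, 33949, 9889 and 14139 bp away, and of the 41 JUNB regions in the highest 0.1%, 17.1% were narrow, against 1.54% of the rest. Of all regions in the highest 0.1%, narrow or not, 65.8% (FOSL2) and 58.5% (JUNB) had a pseudogene within 50 kb. In the rest of the highest 10%, 39.5% and 39.95% did. The test took another set, the narrow regions in the highest 1% of both lists. Of these 14, 11 had a pseudogene within 50 kb, against 39.7% of other strong shared regions (odds ratio 5.57, 1.47 to 31.1, two-sided Fisher's exact p = 0.0045). This is consistent with reads from duplicated sequence as a candidate explanation. Whether the link to pseudogenes is particular to narrow regions was not tested, and no biological explanation was tested.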

How the results depend on the processing

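Alternatives chosen only after seeing the data were leaving out regions narrower than 400 bp, matching on gene length, the whole gene span and counting clustered genes once. Of the values that answer a comparison, 76 kept their direction and side of the threshold or stayed within 1.5 times, and 4 moved: the number of lists above random fell from 6 to 0 for FOSL2 and to 0 for JUNB with a distance of 50 kb, and to 0 for FOSL2 and 0 for JUNB with the 10000 regions of highest fold enrichment. With 50 kb 92.6% and 83.1% of all genes had a region, which leaves little room for an excess. With 10000 regions 13.2% and 14.6% did. The shares behind the equal counts with 10000 regions were not alike. JUNB shares of all its called lists stayed above those of random sets, while FOSL2 shares of its called lists went both ways. These shares rest on few genes, such as 4 of 24 EGF receptor response genes for JUNB and 1 of 20 basal genes for FOSL2. Whether the factors differed was not tested. The cause of the calls lost with 10000 regions was not tested. For single lists, 244 results under alternatives stayed on the same side of the threshold, 33 lost a call and 11 gained one. The 244 include lists that were not called under the main setting and stayed so. All 33 losses fell on the 6 lists called for each factor, each retested under 9 alternatives, so the 244 overstate how stable the calls were. Keratinocyte inflammation gained a call with matching on length for both factors, and for FOSL2 also with narrow regions left out. AP-1 genes gained a FOSL2 call over the gene span, and housekeeping genes gained a JUNB call under 5 of 9 alternatives. The overlap of JUNB regions ranged from 58.5% (10000 strongest of each list) to 89.4% (−log10 q of at least 10), and leaving out narrow regions raised the share of JUNB-only summits near gene ends from 28.3% to 42.5%. No paired analysis was possible because each factor had 1 list for its 3 libraries, and for the same reason no library was left out. The motif tests and their alternatives were not run, since genome sequence was not used here. Depth is unknown, so the difference in list length cannot be set against it.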

Other observations

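None of the tests and counts here was part of the design fixed before the data were examined. The gene list test of shared regions within 10 kb and the counts by window and chromosome were set after region counts and the overlap were seen, but before any gene list result. The gene list tests within 1 kb of gene ends were chosen only after the main results were seen.

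Regions bound by both factors directly at gene ends were frequent in several keratinocyte groups. Within 1 kb of an end, a shared region was present at 13 of 30 suprabasal and junction genes (random sets 16.8%, adjusted permutation p = 0.0096), among them the plakins DSP, EVPL and PPL, the desmosomal cadherins DSC2 and DSG3 and TGM1. Keratinocyte inflammation genes had one in 12 of 28 cases (16.7%, adjusted permutation p = 0.0104), including IL1A, IL1B, IL6, CXCL8, CCL20, PTGS2 and TNFAIP3. Stress and repair genes (9 of 20), EGF receptor response genes (9 of 24), YAP and TEAD targets (8 of 20), basal genes (8 of 20) and cytokine receptor genes (8 of 23) also exceeded random sets, with adjusted p from 0.0144 to 0.0407 in one-sided permutation tests over 16 lists. AP-1 genes (7 of 21), cornified envelope genes (6 of 30), atopic dermatitis locus genes (5 of 39), housekeeping genes (7 of 24), neuronal genes (3 of 18) and fibroblast genes (1 of 18) did not, and melanocyte, T-cell and hepatocyte genes had none, in 15, 18 and 18 genes. JUNB-only regions at gene ends exceeded random sets in no list after adjustment, with 7 of 24 EGF receptor response genes (unadjusted permutation p = 0.0278, adjusted permutation p = 0.413) and 7 of 24 housekeeping genes (unadjusted permutation p = 0.0516) the nearest to it. When shared regions within 10 kb were counted, 7 of the 16 lists exceeded random sets: suprabasal and junction genes (24 of 30), EGF receptor response genes (21 of 24), YAP and TEAD targets, basal genes and stress and repair genes (16 of 20 each), AP-1 genes (15 of 21) and keratinocyte inflammation genes (19 of 28), with adjusted permutation p from 0.0016 to 0.0137.

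The 20 densest windows of 500 kb held 23 to 31 shared regions, against a median of 5 over the 4738 windows with any. The first, on chromosome 2, held 31 and the protein-coding genes LOC107985876, ZFP36L2 and THADA. A window on chromosome 16 with ZFP90, the cadherins CDH3 and CDH1, and TANGO6 held 29, as did one on chromosome 3 with CD96, ZBED2, PLCXD2, PHLDB2, ABHD10 and TAGLN3. Another on chromosome 3 with P3H2, the claudins CLDN16 and CLDN1, and TMEM207 held 28. CCDC88B, SH3TC2, DDX47 and ARL10 each had 7 shared regions within 10 kb of their ends, the most of any gene. These genes and windows were named after their values were seen.

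Chromosomes X and 4 had the lowest shares of FOSL2 regions that were shared with JUNB. Of FOSL2 regions on X 32.3% (95% Wilson interval 30.3 to 34.4) were shared and on chromosome 4 32.9% (31.3 to 34.6), although their fold enrichments alone would give 48.4% and 49.1%. On the other chromosomes the observed share ran from 39.1% to 44.8%. The share given by fold enrichment was above the observed one elsewhere too, as on chromosome 6 (46.1% against 39.1%) and 21 (45.4% against 39.3%). On other chromosomes it was below, as on chromosome 9 (35.9% against 40.9%). The gap was therefore widest on X and 4 but not particular to them, and its cause was not tested. Regions were also sparse on X and 4, with 12.5 FOSL2 and 4.77 JUNB regions per Mb on X and 16.3 and 6.31 on chromosome 4, but chromosome 21 had 15.3 and 7.65.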
